A study of Mus musculus with 3 samples.

How the data were processed

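Translating ribosome affinity purification (TRAP) followed by RNA sequencing was used on the cerebral cortex of adult mice of the Kcnip2-TRAP line NIDA115, on a C57BL/6J background. Such lines express the ribosomal protein L10a fused to green fluorescent protein under the regulatory sequences of a chosen gene, here Kcnip2, so that an antibody to the fluorescent protein pulls down ribosomes, with their messenger RNA, from the cells that express the transgene. Per the labels' protocols, the cortex was homogenized, tagged polysomes were immunopurified with monoclonal antibodies on magnetic beads, and RNA was purified from the immunoprecipitates. The 3 libraries form 1 group of immunopurified samples without treatment, taken from the titles, which also number the replicates. No input, unbound or wild-type library was analysed here, so levels within the immunoprecipitate can be given and enrichment over whole cortex cannot. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The library kit is not given in the sources used here.

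The deposited values are counts of reads per gene symbol, 1 table per library, not normalized by the authors. Per the submitters' processing notes, STAR 2.0.0e and HTSeq were used with the mm10 build. The counting mode, the handling of strand and the annotation release are not given in the sources used here, so reads of overlapping antisense genes, and reads shared by near-identical copies, cannot be separated. Each table has 32531 rows that name a gene, many of them cDNA clones, plus a row named unknown, which held 0 reads, and the counter's special rows. Of all tallied reads, 61.9%, 67.6% and 70.7% fell in genes in replicates 1, 2 and 3. A further 16.4%, 14.2% and 12.8% fell outside any feature, 2.37%, 2.51% and 2.65% were ambiguous, and 19.4%, 15.8% and 13.8% did not align uniquely. These rows were left out of library sizes and tests. No row carried a symbol of a mitochondrial gene, so of 38 gene lists fixed before the data were examined, 37 had at least 1 member. Of the 7 erythroid genes fixed, 4 were in the tables.

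Depth was 11602248, 13635132 and 14174384 gene counts. After TMM scaling (edgeR 4.0.16), 3 counts corresponded to 0.256, 0.222 and 0.213 CPM (counts per 1e6 counts of the scaled library size) in replicates 1, 2 and 3, which is the limit that a count of 0 allows, for counting error only. All 3 pairs of libraries differed by more than sampling noise, with chi-square values of 12.3 to 28.5 per degree of freedom over 12509 genes, so none of them repeats another; separate libraries of 1 RNA sample would differ by more than counting noise as well. The common biological coefficient of variation was 0.197.

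Levels were computed as CPM with TMM-scaled library sizes and as log2 CPM with a prior count of 2. A gene was called detected at 1 CPM or more in all 3 libraries. For each fixed gene list the median log2 CPM of its members was taken in each library, and its percentile was found among 10000 random lists of the same size drawn from the 18703 genes with a read. Within each library, 14 differences between list medians and 26 log2 ratios between pairs of genes, also fixed beforehand, were computed and tested against 0 with an intercept-only limma fit (limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment within each family at 0.05. limma estimated 1 common variance for all contrasts of a family, which gave a standard error of 0.32 for each list contrast and 0.21 for each gene pair, so a contrast whose own libraries spread widely is tested with too small an error. Contrasts of a family share lists or genes and the same 3 libraries, so they are not independent. The small p-values thus rest on less information than the test assumes. An exact sign-flip test of 3 libraries cannot go below p = 0.25. These tests cover the spread between libraries, not the choice of list members. Counts were not divided by transcript length, and exon length is an alternative setting: union exon lengths and positions came from GENCODE M21 on GRCm38, the assembly that mm10 names, matched by symbol for 23155 rows and by an older symbol for 790. Lengths were found for 96.8% of the 12509 genes past the count filter (edgeR's filterByExpr, minimum count 10). A union length covers all annotated exons of a gene and is not the length of the transcript expressed here. Values per kilobase of exon thus show how a result depends on that divisor and do not correct for true transcript length.

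Genes that varied between libraries more than genes of the same level were found with edgeR's quasi-likelihood fit (glmQLFit, robust, intercept-only). The F ratio of a gene's quasi-dispersion to the fitted trend was tested with Benjamini-Hochberg adjustment at 0.05. For gene lists, the range over libraries of the median log2 deviation from the gene's own mean was compared with 10000 random lists matched on level in 20 bins, and called past the 95th percentile. Shares within 6 gene families were taken from summed counts.

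The variance test was tested on simulated counts for 12509 genes with the libraries' own means and sizes. Every simulated gene had the same coefficient of variation, the common value of 0.197. The test recovered 4% of 50 genes changed 2-fold in 1 library, 86% of 50 changed 4-fold and all of 50 changed 8-fold, and called 0 unchanged genes. As the simulated genes did not differ in variation, this does not give the rate of false calls among real genes. The contrast test, on 40 simulated gene pairs for each ratio, called 36 pairs with a true log2 ratio of 1, 14 with a ratio of 0.5, 3 with a ratio of 0.25 and 3 with a ratio of 0, and so calls some pairs that do not differ. The simulated pairs also shared 1 coefficient of variation. The SD of the real pairs ran from 0.06 (Scn8a minus Scn1a) to 1.01 (Pvalb minus Sst), so the simulation does not show the error for pairs of wide spread.

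Alternatives were a prior count of 0.5, means in place of medians, only members past the count filter, DESeq2 size factors (DESeq2 1.42.0), values per kilobase of exon, other detection thresholds, other variance tests, and leaving out each library in turn. The genes named in the text follow a rule fixed beforehand: the genes of the pairs, the Kv4 complex and the sex-linked list, up to 4 members with the highest and 1 with the lowest mean of each other list, the 10 most abundant genes and up to 10 variable genes. The few others named were chosen after their values were seen, and the text says so. A few genes that this rule picks, and 2 of the pairs, are not reported here.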

Results

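RNA immunopurified with tagged ribosomes from Kcnip2-TRAP cortex was profiled in 3 libraries of 1 group. The line tags ribosomes in cells that use the regulatory sequences of Kcnip2, which encodes KChIP2, an auxiliary subunit of Kv4 potassium channels. The libraries held 11602248, 13635132 and 14174384 gene counts in replicates 1, 2 and 3. A total of 12130 genes were detected at 1 CPM or more in all 3 libraries, and 1872 genes reached 100 CPM in each. The questions that this design allows are which genes the immunoprecipitates held, background included, how related genes compared within a library, and how the replicates differed. Values are CPM ± SD over n = 3 libraries unless stated otherwise.

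Neuronal transcripts were the most abundant markers in the immunoprecipitates, and markers of other cell types lay lower. Snap25, a synaptic vesicle fusion protein, was the most abundant gene at 33507 ± 2339 CPM, and Syn1 and Syt1, which encode synaptic vesicle proteins, and the neurofilament gene Nefm reached 3940.1 ± 489.8, 1743 ± 127 and 1503 ± 142 CPM. The lowest of the 11 pan-neuronal genes was Tubb3, a neuronal tubulin, at 66.4 ± 9.62 CPM. The median pan-neuronal gene was 15.7-fold above the median of 12 astrocyte genes (log2 difference 3.98 ± 0.29 SD, n = 3, limma adjusted p = 1.21e-12), 31.0-fold above oligodendrocyte genes (log2 4.96 ± 0.24), 51.6-fold above oligodendrocyte precursor genes (log2 5.69 ± 0.15), 117-fold above microglial genes (log2 6.88 ± 0.38) and 246-fold above endothelial and mural genes (log2 7.94 ± 0.20). Each difference was positive in 3 of 3 libraries and passed the limma test. The folds depend on length and on the summary: per kilobase of exon the log2 difference was 6.83 for precursor genes and 5.76 for microglial genes, the other order, and for microglial genes it was 8.15 by means and 6.17 with members past the count filter.

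Several glial genes were nonetheless abundant. Among astrocyte genes, the glutamate transporter Slc1a2 was at 1332 ± 297 CPM, the glutamine synthetase gene Glul at 1324 ± 318, the glycolytic gene Aldoc at 529 ± 144 and Atp1b2 at 458 ± 98.3, whereas Aldh1l1 was at 7.45 ± 2.19. Of the myelin genes, Mbp was at 138 ± 35.2 CPM and Cnp at 126 ± 25.7, and Opalin was at 0.893 ± 0.524. Microglial Csf1r and Cx3cr1 were at 19.8 ± 8.30 and 14.5 ± 3.003 CPM, and Tyrobp was at 0.247 ± 0.303. The pericyte marker Rgs5 was at 8.10 ± 2.08 CPM and the endothelial tight junction gene Cldn5 at 0.0568 ± 0.0984, below the counting limit. The choroid plexus transcript Ttr averaged 14.01 CPM with an SD of 24.3 CPM, as all 569 of its counts were in replicate 2. The 4 erythroid genes measured were all below 2 CPM, with Hbb-bs the highest at 1.58 ± 0.820. Without an input library, these levels do not separate background RNA from expression in tagged cells.

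**Figure D1:**
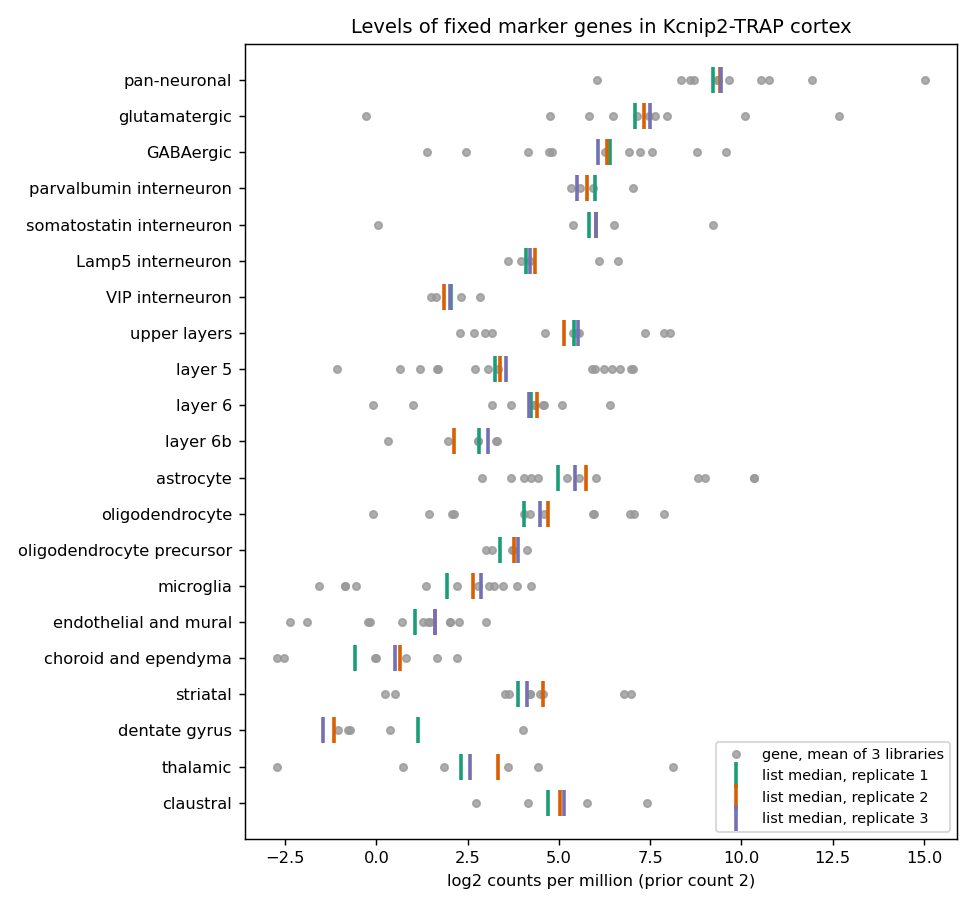
Levels of the fixed marker genes. The horizontal axis is log2 CPM; grey points are single genes (mean of 3 libraries) and coloured bars are the list median in replicates 1, 2 and 3. The pan-neuronal medians lie to the right of every non-neuronal list. In most lists single genes spread far more than the libraries do, which is less clear for the dentate gyrus and oligodendrocyte precursor lists.

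Markers of both excitatory and inhibitory neurons were well represented. Among glutamatergic genes, the kinase gene Camk2a was at 6526 ± 947 CPM, the vesicle protein gene Sv2b at 1119 ± 226 and the vesicular glutamate transporter Slc17a7 at 249.9 ± 47.4, while the cortical homeobox gene Emx1 was at 0.710 ± 0.355. Among GABAergic genes, the GABA-synthesizing enzymes Gad2 and Gad1 were at 767 ± 24.6 and 439.96 ± 45.8 CPM, the interneuron transcription factor Lhx6 at 189.6 ± 35.4, the receptor gene Erbb4 at 149.7 ± 14.2, and Dlx6 was the lowest at 2.52 ± 0.627. The glutamatergic list median was 2.06-fold above the GABAergic one (log2 1.04 ± 0.38 SD, higher in 3 of 3 libraries, limma adjusted p = 0.00318). Gene by gene, Slc17a7 was below Gad1 in all 3 libraries (log2 ratio -0.83 ± 0.40, limma adjusted p = 0.000334), a call that ended per kilobase of exon (log2 ratio -0.33, adjusted p = 0.154). Slc17a7 was 11.6-fold above Slc17a6, the vesicular glutamate transporter gene of subcortical neurons (limma adjusted p = 5.06e-22).

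Interneuron marker genes differed widely in level. The list medians were at log2 CPM 5.95 ± 0.11 for somatostatin, 5.76 ± 0.26 for parvalbumin, 4.21 ± 0.13 for Lamp5 and 1.97 ± 0.10 for VIP interneuron genes (SD, n = 3), and these lists were not tested against each other. As single genes, Sst, which encodes somatostatin, was at 625 ± 242 CPM, against 137 ± 50.7 for the calcium-binding protein gene Pvalb and 7.22 ± 1.97 for the peptide gene Vip. Sst exceeded Vip by a log2 ratio of 6.37 ± 0.53 (limma adjusted p = 8.17e-34; 8.61 per kilobase of exon) and Pvalb by 2.18 (Pvalb minus Sst, -2.18 ± 1.01, limma adjusted p = 6.94e-14), each in 3 of 3 libraries. With limma's robust moderation, which lets the wide spread of Pvalb and Sst count, the adjusted p for that pair was 0.0569. All 4 members of the VIP list, with Calb2, Tac2 and Crh, were between 2.68 and 7.22 CPM. Of the Lamp5 list, Lamp5 was at 98.2 ± 6.58 CPM and Reln at 68.8 ± 5.77, and Ndnf was the lowest at 12.3 ± 2.20.

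Markers of all cortical layers were present, with upper-layer genes highest as a list. The upper-layer transcription factor genes Cux1 and Rorb were at 263 ± 17.3 and 164 ± 28.2 CPM, and Rasgrf2 was at 235 ± 35.2. Layer 5 genes included Parm1 at 131 ± 16.5, Bcl6 at 127 ± 22.6, Etv1 at 103 ± 16.8 and the subcerebral projection neuron factor Fezf2 at 64.5 ± 11.1. Layer 6 genes included Tle4 at 84.9 ± 5.19 and Foxp2 at 34.7 ± 7.90, and the 6 layer 6b genes ranged from 1.10 CPM for Nxph4 to 10.1 for Inpp4b. The upper-layer median exceeded the layer 5 median by 1.96 ± 0.21 on the log2 scale (limma adjusted p = 1.83e-06; 1.14 by means, 0.75 with members past the count filter and 0.73 per kilobase of exon, adjusted p = 0.0354) and the layer 6 median by 1.09 ± 0.32 (limma adjusted p = 0.00238), and layer 6 exceeded layer 6b by 1.59 ± 0.60 (limma adjusted p = 3.97e-05), each in 3 of 3 libraries. Upper-layer over layer 6 ended per kilobase of exon (log2 0.65, adjusted p = 0.0567). Layer 5 lay below layer 6 by medians (log2 -0.87 ± 0.23, limma adjusted p = 0.0110) and above it by means (log2 0.19, adjusted p = 0.412), so no order of these layers holds. Fezf2 was 1.87-fold above Foxp2 (log2 ratio 0.90, and 3.33 per kilobase of exon) and Cux2 was below Rorb (log2 ratio -1.84 ± 0.20), each in all 3 libraries.

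Transcripts typical of neighbouring regions were lower than glutamatergic cortical ones. The glutamatergic median exceeded the striatal median by 3.11 ± 0.31 on the log2 scale (limma adjusted p = 2.87e-10) and the thalamic median by 4.57 ± 0.51 (limma adjusted p = 4.71e-14). Of the striatal genes, the enkephalin precursor Penk was at 129 ± 39.5 CPM and Pde10a at 111 ± 22.7, whereas Gpr6 was at 1.10 ± 0.547. Rora stood out in the thalamic list at 277 ± 10.4 CPM, and Gbx2 had 0 counts in all 3 libraries. Of 5 dentate gyrus genes, Prox1 was at 16.2 ± 2.71 CPM and was the only member at 1 CPM or more in every library. Nr4a2, a claustrum and deep-layer transcription factor gene, was at 171 ± 20.03 CPM. The levels of these genes, Penk, Pde10a and Rora included, do not separate RNA of neighbouring regions from expression in cortical cells.

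Among genes of the Kv4 channel complex, no KChIP gene was the highest in all 3 libraries: Kcnip2 led in replicate 1, at 189 CPM against 180 for Kcnip3 and 168 for Kcnip4, and Kcnip3 in replicates 2 and 3. Kcnip2 (chromosome 19, 45791839 to 45816061, minus strand, mm10) was at 164 ± 21.9 CPM, Kcnip3 (chromosome 2, 127456498 to 127522094) at 230.3 ± 43.9, Kcnip4 (chromosome 5, 48389502 to 49524907) at 179 ± 12.3 and Kcnip1 (chromosome 11, 33629339 to 33993152) at 95.1 ± 8.07. Kcnip2 supplied 24.7% ± 4.33 (SD, n = 3) of the counts of the 4 KChIP genes, Kcnip3 34.3% ± 5.39, Kcnip4 26.7% ± 0.856 and Kcnip1 14.3% ± 1.65. Kcnip2 exceeded Kcnip1 in 3 of 3 libraries by 0.78 ± 0.13 on the log2 scale (limma adjusted p = 0.00055), and by 1.62 per kilobase of exon. Kcnip2 was above Kcnip3 in 1 of 3 libraries and the mean log2 ratio was -0.47 ± 0.48, a call by limma (adjusted p = 0.0301) that was lost without replicate 2 (log2 -0.36, adjusted p = 0.286) or replicate 3 (log2 -0.32, adjusted p = 0.222). Kcnip2 and Kcnip4 did not differ by the test (log2 ratio -0.13 ± 0.28, limma adjusted p = 0.541).

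Of the pore-forming Kv4 subunits, Kcnd3 was at 92.6 ± 8.02 CPM, Kcnd2 at 68.6 ± 4.11 and Kcnd1 at 7.45 ± 1.16. Kcnd2 exceeded Kcnd1 by 3.19 ± 0.16 on the log2 scale (limma adjusted p = 2.90e-20). Kcnd2 was below Kcnd3 by counts (log2 ratio -0.43 ± 0.16, limma adjusted p = 0.0476). That call was lost without replicate 2 (limma adjusted p = 0.232) or replicate 3 (limma adjusted p = 0.167). Per kilobase of exon Kcnd2 was above Kcnd3 (log2 ratio 0.47, limma adjusted p = 0.0404). Their order thus depended on whether counts were divided by union exon length. The auxiliary subunit genes Dpp6 and Dpp10 were at 283 ± 10.02 and 132 ± 29.5 CPM, a log2 ratio of 1.12 ± 0.28 (limma adjusted p = 3.24e-06).

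**Figure D2:**
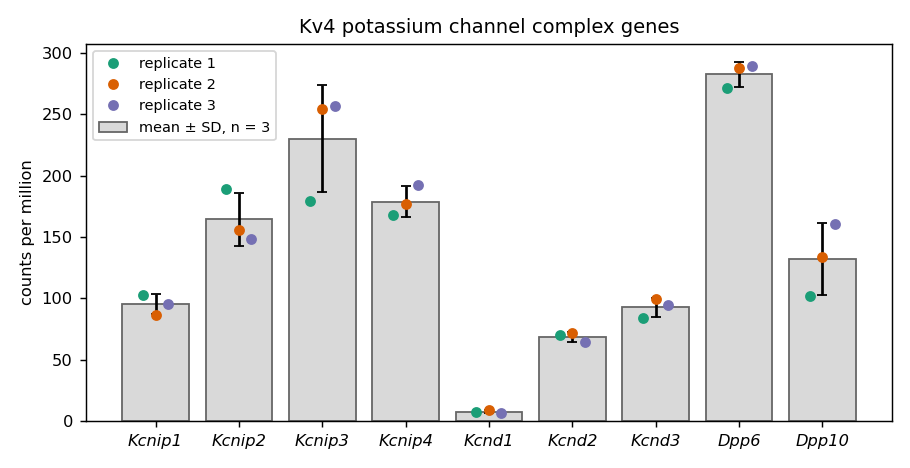
Kv4 complex genes. Bars are the mean CPM, whiskers the SD and points the 3 replicates; the vertical axis starts at 0. Kcnip2 lies between Kcnip1 and Kcnip4 by mean, and replicate 1 holds the highest Kcnip2 and the lowest Kcnip3 value.

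The Kv4 complex, other potassium and Hcn channel, and sodium and calcium channel lists were among the more abundant parts of the profile. So were the ionotropic glutamate and GABA-A receptor lists, and each of these lists lay at the 99.67 percentile of random lists of its size or above. The sodium channel gene Scn8a was at 1523 ± 46.6 CPM, Scn1a at 417 ± 28.8 and Scn2a1 at 242 ± 30.1. Scn8a exceeded Scn1a by 1.87 ± 0.06 on the log2 scale (limma adjusted p = 8.85e-12) and Scn2a1 was below Scn1a (log2 ratio -0.79 ± 0.19, limma adjusted p = 0.000538). The potassium channel genes Kcna2 and Kcnc1 were at 761 ± 23.1 and 527 ± 62.2 CPM. Calcium channel gene Cacna1e was at 396 ± 46.7 CPM and Cacna1a at 198 ± 8.44, a log2 ratio of 0.99 ± 0.23 (limma adjusted p = 2.60e-05) that turned to -0.15 per kilobase of exon.

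Among AMPA receptor counts, Gria3 had 46.6% ± 1.23 (SD, n = 3) and Gria2 30.2% ± 2.24; per kilobase of exon Gria2 fell to 18.6%, below Gria1 at 19.8%. Gria2 exceeded Gria1 by a log2 ratio of 1.27 ± 0.28 (limma adjusted p = 2.50e-07), which turned to -0.09 per kilobase of exon. Of the NMDA receptor subunits, Grin1 was at 271 ± 44.5 CPM, and Grin2b exceeded Grin2a in all 3 libraries (Grin2a minus Grin2b, log2 ratio -2.16 ± 0.27, limma adjusted p = 8.76e-14), with Grin2b supplying 75.6% ± 1.61 of Grin2 counts (59.1% per kilobase of exon). Gabra6, a GABA-A receptor subunit gene of cerebellar granule cells, had 0 counts in all 3 libraries, which allows up to 0.213 to 0.256 CPM. Grm5 led the metabotropic glutamate receptors at 187 ± 15.6 CPM.

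**Figure D3:**
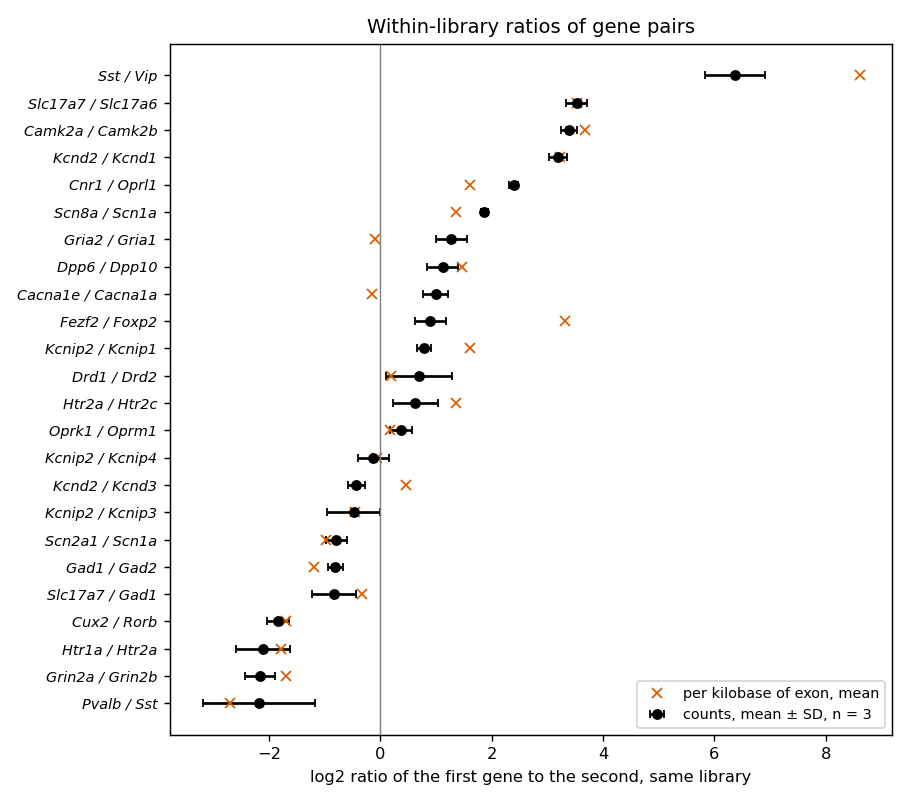
Within-library ratios of 24 of the 26 fixed gene pairs. Points are the mean log2 ratio of counts with SD whiskers over 3 libraries, and crosses are the same ratio per kilobase of exon. Crosses lie on the other side of 0 for Gria2 over Gria1, Cacna1e over Cacna1a and Kcnd2 over Kcnd3.

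Lists of neuromodulator receptor genes lay nearer the middle of random lists of their size than the ion channel lists, at the 27.1 percentile for serotonin, 61.09 for catecholamine, 62.13 for cholinergic and 74.57 for opioid and cannabinoid receptors. The cholinergic list held nicotinic channel genes (Chrna and Chrnb) beside muscarinic ones, and the serotonin list held the channel gene Htr3a. The contrast thus depends in part on how genes were assigned to lists. Htr5a and Htr2a led the 13 serotonin receptors at 84.3 ± 4.64 and 47.99 ± 3.92 CPM, followed by Htr2c at 31.7 ± 8.76 and Htr1a at 11.3 ± 2.93. Htr2a exceeded Htr2c (log2 ratio 0.63 ± 0.40, limma adjusted p = 0.00473; 1.36 per kilobase of exon) and Htr1a was below Htr2a (log2 ratio -2.11 ± 0.48, limma adjusted p = 1.72e-13), each in 3 of 3 libraries. Adra1a led the catecholamine receptors at 61.3 ± 4.996 CPM. Drd1 and Drd2 were at 18.6 ± 2.34 and 12.4 ± 6.29 CPM, a log2 ratio of 0.70 ± 0.60 (limma adjusted p = 0.00182) that did not pass without replicate 1 (log2 0.38, adjusted p = 0.0525) or per kilobase of exon (log2 0.19, adjusted p = 0.435). The cannabinoid receptor gene Cnr1 was at 87.2 ± 5.41 CPM and exceeded the nociceptin receptor gene Oprl1, at 16.5 ± 1.87, by 2.39 ± 0.08 on the log2 scale (limma adjusted p = 2.49e-15; 1.61 per kilobase of exon). Oprd1, Oprk1 and Oprm1, the delta, kappa and mu opioid receptor genes, were at 55.4 ± 9.88, 6.57 ± 1.13 and 5.09 ± 1.14 CPM, and Oprk1 and Oprm1 did not differ by the test (log2 ratio 0.37 ± 0.20, limma adjusted p = 0.0853). Chrm1 led the cholinergic receptors at 81.1 ± 6.44 CPM, and among neuropeptides Cck, at 575 ± 78.6 CPM, was next to Sst.

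Over the whole family of pairs, the first gene was higher in 15 of 26 and lower in 9 by limma, and 2 did not pass. Of the 14 list contrasts, 13 were positive and 1 negative. Because no length correction was applied and the choice of list members sets the medians, these calls rank reads within these libraries only.

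The 10 most abundant genes, among them Snap25, Rn45s, Vsnl1, Ywhaz, Kalrn, Camk2a, Map1b, Cdr1 and Malat1, together took 11.3%, 10.3% and 9.99% of gene counts in replicates 1, 2 and 3. Vsnl1, a neuronal calcium sensor gene, was at 11597 ± 684 CPM and Rn45s, the ribosomal RNA precursor, at 20368 ± 4869. Reads at Cdr1 (4625 ± 1821 CPM) cannot be assigned to a strand, and an abundant brain circular RNA is transcribed antisense to this gene. The 81 ribosomal protein genes had a median of 34.7 CPM; Rpl10a, whose coding sequence is part of the tag and which was chosen after its value was seen, was at 71.99 ± 11.8 CPM, and Rpl4, the highest, at 419 ± 27.6.

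Between replicates, a small set of genes varied far more than others of the same level. Of 12509 genes, 11 passed edgeR's quasi-dispersion test, and 9 of these were highest in replicate 1. The count depended on the setting, from 4 without replicate 2 to 66 with no count filter. Malat1, a nuclear non-coding RNA, was at 8782, 2578 and 1801 CPM in replicates 1, 2 and 3 (adjusted p = 2.95e-08), and the small nucleolar RNA host gene Snhg11, which the annotation used here classes as protein-coding, was at 815, 208 and 152 CPM (adjusted p = 2.37e-08). Meg3, another nuclear non-coding RNA, was at 1022, 727 and 460 CPM (edgeR adjusted p = 0.0199). Of the 10 with the largest F ratio, A330076H08Rik, BC057675, AI506816, Cdr1 and Mad1l1 were also highest in replicate 1. Sst, at 429, 551 and 895 CPM (edgeR adjusted p = 0.0281), and Ptgs2, an activity-regulated cyclooxygenase gene, at 20.5, 46.5 and 65.7 CPM (edgeR adjusted p = 0.0346), were lowest in replicate 1.

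Gene lists moved between replicates as well, in 12 of 35 lists by more than 95% of matched random lists. Nuclear non-coding RNAs had median log2 deviations of 0.52, -0.06 and -0.52 in replicates 1, 2 and 3, and parvalbumin interneuron genes 0.47, -0.09 and -0.30. In replicate 1 the median deviation was -0.35 for astrocyte genes, -0.36 for immediate early genes such as Egr1 and Arc, -0.54 for endothelial and mural genes, -0.38 for somatostatin interneuron genes and -0.23 for glutamatergic genes. The somatostatin value is the median of only 3 genes. Of these, Crhbp went the other way, at 45.6, 41.2 and 39.1 CPM in replicates 1, 2 and 3. Oligodendrocyte and striatal genes were highest in replicate 2, at 0.27 and 0.32. Reads outside features made up 16.4% of tallied reads in replicate 1 against 14.2% and 12.8% in the others. Without replicate 1, 7 lists passed, and the astrocyte, immediate early, endothelial and mural, parvalbumin, somatostatin and ribosomal protein lists were no longer among them.

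**Figure D4:**
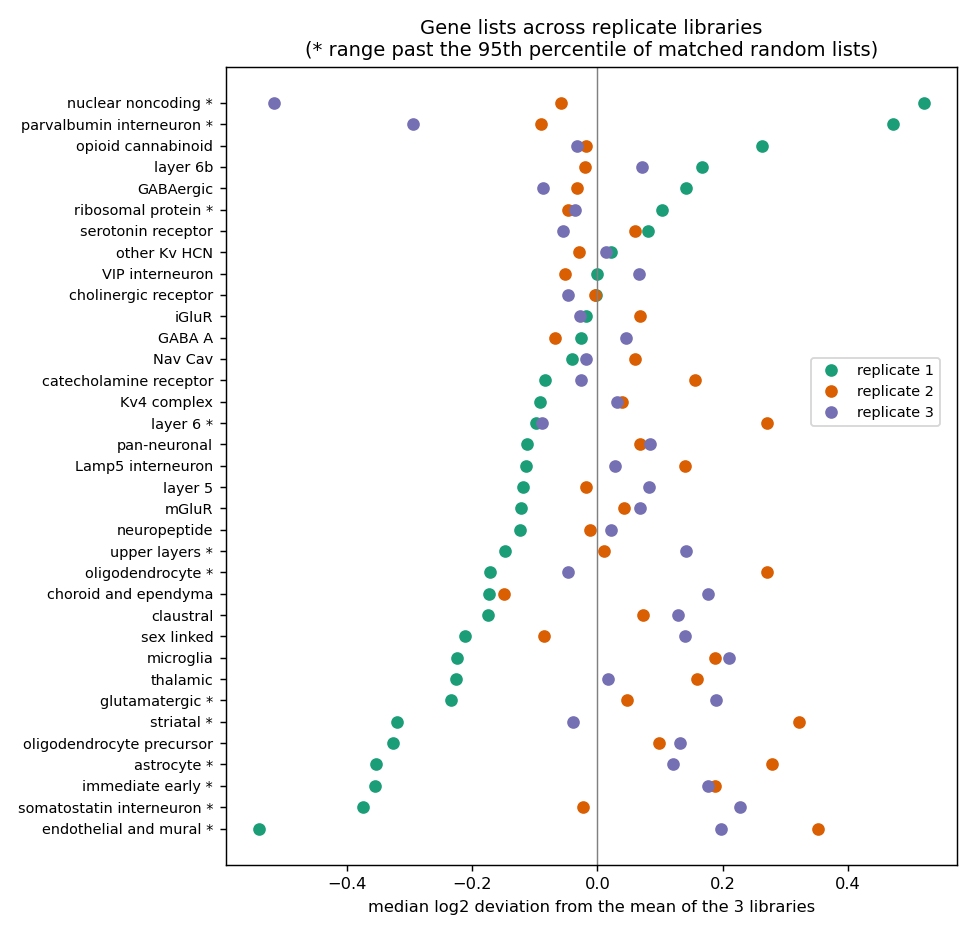
Gene lists across replicates. The horizontal axis is the median log2 deviation of list members from their mean over the 3 libraries, with 1 point per replicate; an asterisk marks a range past the 95th percentile of level-matched random lists. Replicate 1 lies at one end for most starred lists, from -0.54 for endothelial and mural genes to 0.52 for nuclear non-coding RNAs.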

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

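All calls below rest on 3 libraries. The number of detected genes lay between 12130 and 14084 under all thresholds, scalings and left-out libraries tried. The number of lists above the 95th percentile of random lists, 14, lay between 10 and 18. A prior count of 0.5 changed no call of a list or pair, and DESeq2 size factors no call on a list's range. Layer 5 minus layer 6 was the least stable contrast: its log2 value of -0.87 became 0.19 with means over members, 0.22 with members past the count filter only and -0.0827 per kilobase of exon, so that 0 negative list contrasts were left in each case, and 12 positive ones per kilobase of exon, where upper-layer minus layer 6 fell short at 0.65. With each library left out, layer 5 minus layer 6 lay between -0.81 and -1.004, passing in all but 1 case (without replicate 2, adjusted p = 0.0976), and the number of negative list contrasts between 0 and 1. Per kilobase of exon, Kcnd2 minus Kcnd3 (0.47), Gria2 minus Gria1 (-0.0893) and Cacna1e minus Cacna1a (-0.15) changed sign, and the KChIP shares became 8.70% for Kcnip1 and 27.9% for Kcnip4, as exon lengths differ; 20 of 25 family shares moved by more than 1 SD. The 11 variable genes became 66 with no count filter, 28 as DESeq2 dispersion outliers, which held all 11, and 4 to 9 with 1 library left out; the cause was not tested. Without replicate 1, 9 genes passed, 3 of them among the 11, and without replicate 2, 4 passed. After seeing the data, leaving out Rn45s and Malat1 and a robust moderation in limma were added, as were left-out libraries for the lists' ranges: 7 lists passed without replicate 1 and 13 and 11 without replicates 2 and 3. Kcnd2 minus Kcnd3 was also lost without replicate 2 (adjusted p = 0.232) or replicate 3 (adjusted p = 0.167), and Oprk1 minus Oprm1 passed without replicate 1 (adjusted p = 0.0452). No paired analysis was possible because there is only 1 group. Depth limits genes under about 0.2 CPM, and a 2-fold change in 1 library was rarely recovered in simulated data.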

Other observations

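The tests on depth, on non-neuronal markers, on scaling and on sex-linked genes below were chosen after the result was seen. Xist, the RNA of the inactive X chromosome in females, was counted at 180, 203 and 170 reads in replicates 1, 2 and 3, and the Y-linked genes Ddx3y (21.6 ± 5.63 CPM), Kdm5d (10.8 ± 2.56), Uty (9.39 ± 1.48) and Eif2s3y (4.32 ± 0.874) were present in each library as well. RNA of both sexes in each library and carry-over from libraries not analysed here cannot be told apart: the lowest Xist count, 170, only restates the pattern, and the labels give no sex.

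The first pattern is the excess of Malat1, Snhg11 and Meg3 in replicate 1. The smaller depth of that library is argued against, since fewer reads do not raise raw counts and those of all 3 genes were highest there, by 2.95-fold for Malat1, 3.40-fold for Snhg11 and 1.22-fold for Meg3 over the next library. A hypothesis is that more nuclear or unspliced RNA was carried into replicate 1, and the test, planned before its result was seen, went with it: 222 annotated non-coding genes outside the nuclear non-coding list had a median log2 deviation of 0.115 in replicate 1, above all 10000 level-matched random sets, and reads outside features per gene read were 0.265 there against 0.210 and 0.182. The deviation in the other libraries was -0.13 and -0.01, so the shift is small beside that of Malat1. Ribosomal protein genes, which are coding, had a median deviation of 0.103 in replicate 1, so a shift of this size is not particular to non-coding RNA and the explanation stays open. No biological explanation was tested.

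The second pattern is the lower level of non-neuronal markers in replicate 1. Of 44 members of the astrocyte, oligodendrocyte, precursor, microglial, and endothelial and mural lists, 39 were below their mean in replicate 1, against a median of 22 in matched random sets, and all 5 lists had a negative median. Less RNA from non-neuronal cells in that library is a candidate explanation, but the same lists showed the pattern, so the count gives it no independent support. Scaling by the abundant Rn45s and Malat1 is argued against. With both left out before TMM scaling, the call on the range was the same for all 35 lists. Their share of the unscaled library totals allows a log2 shift of only -0.0121 in replicate 1, against a median astrocyte deviation of -0.35. That shift describes scaling by totals and not TMM scaling. Most of the 35 lists had negative medians in replicate 1, so lower values there were not confined to non-neuronal markers. Among them were the immediate early, glutamatergic, somatostatin, pan-neuronal, upper-layer, layer 5, striatal and thalamic lists. The sign of the median thus does not set the 5 non-neuronal lists apart. The ranges of the precursor and microglial lists, at the 85.79 and 90.4 percentile of matched random lists, were not called. Parvalbumin (0.47) and GABAergic (0.14) lists were among those with positive medians in replicate 1. The state of the animals or the dissection stays open.

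The third pattern is that some list members lay far below related genes, such as Emx1 in the glutamatergic list and Cldn5 in the endothelial and mural list. Over 315 list members, levels centred on their list rose with exon length (Spearman rho = 0.381, Pearson r = 0.374, permutation p = 1e-04, adjusted 0.00015). They fell with GC content (rho = -0.243, r = -0.254, permutation p = 1e-04, adjusted 0.00015). Over 12090 genes past the count filter, levels also rose with exon length (rho = 0.329) and fell with GC content (rho = -0.166). Both relations had permutation p = 1e-04, adjusted 0.00015. The value 1e-04 is the smallest p that 10000 permutations can give, and 6 relations were computed. Transcript length may play a part. Among 77 ribosomal protein genes, however, the relation with exon length was weaker and did not pass (rho = 0.189, permutation p = 0.101). For length, passing among these genes was not a condition set beforehand. For GC content the second condition set beforehand was not met: among 77 ribosomal protein genes rho was -0.169 (permutation p = 0.14), so a GC bias of the libraries cannot be told apart from lower expression of GC-rich genes. Members under 1 CPM were counted in 4 bins of rising GC content (up to 45%, 50%, 55% and above). They were 4 of 71, 6 of 75, 16 of 84 and 6 of 85. The very low members as a set thus did not gather in the GC-richest bin. This tally was not centred on the list. Median levels relative to the list were 0.69, 0.38, -0.33 and -0.33 in the same 4 bins, so levels were lower above 50% GC. However, Emx1 (66.82% GC) and Cldn5 (60.45% GC), the examples named above, were both in the GC-richest bin, so the tally does not settle their case. The relations with exon length and GC content are correlations across genes, which are not independent replicates.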
